A study of Micropterus salmoides with 6 samples.

How the data were processed

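RNA was taken from whole bodies of largemouth bass larvae, in 6 libraries each made from a pool of 30 larvae. Per the labels' protocols, total RNA was extracted with a mirVana kit, checked for integrity, made into stranded mRNA libraries with a TruSeq kit and sequenced as paired ends on an Illumina HiSeq instrument. Per the submitters' processing notes, Trimmomatic, HISAT2, Bowtie2, SAMtools, StringTie, Cufflinks, HTSeq and DESeq were used; their roles and versions are not given in the sources used here. The same notes name a mouse genome build, although the gene names are those of largemouth bass. Because of this conflict no coordinates are given. The deposited counts are whole-number counts per gene, not normalized, with 1 column per library. The deposited FPKM values equal those counts divided by a gene length and by the library's total: the implied length of each of 24734 genes with counts in several libraries was the same in all of them, within 1 part in 10000. Of the gene IDs, 27161 matched symbols of the largemouth bass RefSeq table used for names (assembly ASM1485139v1) and 5 that read as dates did not. Of all the IDs, 13325 are LOC numbers without a descriptive name, so the parts of the gene lists that rest on product names could not be used.

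Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and the groups were compared by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Counts are also given at a fold of at least 2. No replicate block was used. DESeq2 1.42.0 and limma 3.58.1 (voom, and limma with a trend on log2 of the deposited FPKM plus a pseudocount of 1 or 0.1) served as alternatives. The deposited totals were between 14958887 and 16922264 counts per library, and the median biological coefficient of variation was 13.5%. Counts of replicates differed by 11 to 15 times the sampling variance, so no library was a repeat of another, the spread between pools exceeded counting error, and p-values measure that spread.

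Before the data were examined, 29 gene lists, 12 skeletal markers, the tests and the alternatives were fixed. Lists with at least 5 tested members were tested by camera with a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2), beside camera with an estimated correlation and fry, with adjustment over the lists. Named genes were up to 10 higher and 10 lower genes with the largest change among those called with a log2 CPM of at least 1, no overlap between groups and a name; in each list up to 4 called members with the lowest p, or the member with the lowest p; and the skeletal markers. This gave 4 genes under its first part. Further members with the lowest DESeq2 adjusted p (up to 4 per list), the LOC genes and the genes named in the closing section outside these were chosen after their values were seen.

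The alternatives were RLE scaling, library size alone, DESeq2, limma-voom, 2 other filters, the replicate number as a block, leaving out each library, a test against a fold of 1.5 and the FPKM fits. After the data were seen, robust variance estimation and a fit without the 20 most abundant genes were added, as were 8 gene lists, which were also tested without each library in turn. The steps were tested on simulated data with the means, dispersions and library sizes of these 20627 genes and 200 changed genes, in 3 simulations. The changed genes were drawn from those with a mean of at least 2 CPM, so recovery at lower levels was not measured. For SP_L against SP_H, edgeR recovered 21.0% of simulated 1.5-fold changes, 75.3% of 2-fold and 92.7% of 3-fold changes, and 9.48% of its scored calls were false. DESeq2 recovered 37.3%, 82.0% and 93.3%, and 22.4% of its scored calls were false. Simulated genes vary independently, so the simulation does not test the list calls against correlation between genes.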

Results

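Whole-body gene expression was measured by RNA sequencing in larvae of the largemouth bass (Micropterus salmoides), a farmed freshwater fish. Larvae had been fed for 12 days. The SP_L group consisted of larvae with visible skeletal deformity that had received a diet with 0% phospholipid, and the SP_H group of normal larvae that had received a diet with 8% phospholipid. Each group had 3 libraries, and each library was a pool of 30 larvae from a tank. The 6 libraries held between 14958887 and 16922264 counts over 27166 genes, and 20627 genes had enough counts to be tested. Deformed larvae were picked for one group and normal larvae for the other, so diet and deformity divide the libraries in the same way and every difference below belongs to both together. Fold changes are given as log2 of SP_L over SP_H, with the standard error of the edgeR fit, and levels as CPM, read counts scaled to the size of the library, with the SD over 3 libraries.

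The comparison asked which genes differ between deformed larvae without dietary phospholipid and normal larvae with it. A small number of genes passed the gene test, most of them higher in SP_L. The muscle ubiquitin ligase gene fbxo32, known for its part in muscle protein breakdown, rose from 12.4 ± 6.70 to 89.7 ± 36.4 CPM (SD, n = 3 each), a log2 fold change of 2.85 ± 0.37 (edgeR adjusted p = 0.0446). The stress-response pseudokinase gene trib3 rose from 20.8 ± 2.80 to 40.9 ± 2.01 CPM, a log2 fold change of 0.98 ± 0.11 (edgeR adjusted p = 0.0291). The muscle creatine kinase gene ckma rose by 0.78 ± 0.10 on the log2 scale (edgeR adjusted p = 0.0412). The gene zgc:112285 fell from 26.7 ± 2.09 to 11.7 ± 2.49 CPM, a log2 fold change of -1.19 ± 0.15 (edgeR adjusted p = 0.0440). In each of these 4 genes the libraries of one group did not overlap those of the other, which was a condition for choosing them. Of all tested genes 19.1% had groups without overlap, and chance gives 10%. All 4 calls were lost without any 1 of SP_H replicate 2, SP_H replicate 3, SP_L replicate 1, SP_L replicate 2 or SP_L replicate 3, with edgeR adjusted p-values between 0.0536 and 0.161, and that of ckma also without SP_H replicate 1 (adjusted p = 0.0580). No direction changed. With library size alone the calls of fbxo32, trib3 and ckma were lost (edgeR adjusted p = 0.0533), with robust variance estimation that of fbxo32 (0.124), and in the limma fits of FPKM all 4 (adjusted p between 0.0760 and 0.142). A test against a fold of 1.5 called none of the 4 (edgeR glmTreat, smallest adjusted p = 0.251).

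**Figure D1:**
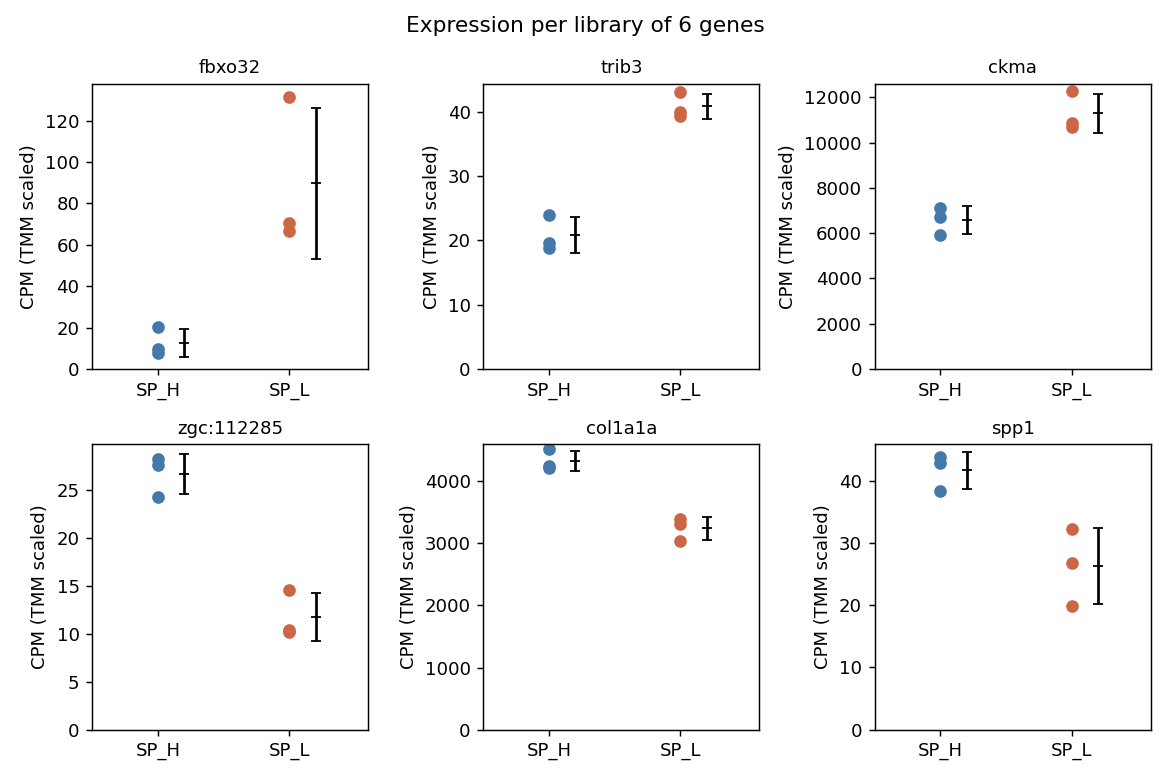
CPM (TMM scaled, vertical axes from 0) of 6 genes in the 3 SP_H and 3 SP_L libraries; points are libraries and bars are the mean ± SD. The groups do not overlap in any of the 6 genes, nor in 19.1% of all tested genes. Of the 6, fbxo32, trib3, ckma and zgc:112285 passed the edgeR test and col1a1a and spp1 did not.

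In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 14 genes, 12 higher and 2 lower in SP_L, and 10 of them had a fold of at least 2. The other 10 called genes carry a LOC number without a name. Of these, LOC119886167 had a log2 fold change of 3.97 ± 0.46 and LOC119893217 one of -0.86 ± 0.11. The call of LOC119886167 was lost with limma-voom (adjusted p = 0.0711). At an unadjusted p under 0.05 the test counted 2629 genes, 1424 higher and 1205 lower, against 1031 expected by chance. DESeq2 called 449 genes, of which 326 (72.6%) were higher in SP_L and the rest lower, including all 14 of the edgeR calls. The edgeR count depended on single libraries: it was 22 without SP_H replicate 1, 1 without SP_H replicate 2, 0 without SP_H replicate 3, 0 without SP_L replicate 1, 6 without SP_L replicate 2 and 2 without SP_L replicate 3. With library size alone as the scaling it was 3 higher and 2 lower, and the median log2 fold change of all genes moved to -0.13.

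Most bone matrix genes were at lower levels in SP_L, without any passing the edgeR test. Among the 30 tested genes of the osteoblast and bone matrix list, 25 had negative log2 fold changes. The median was -0.24 (-0.36 with library size alone). The chains of type I collagen, the main fibre of bone matrix, had log2 fold changes of -0.44 ± 0.08 for col1a1b, -0.42 ± 0.08 for col1a1a and -0.41 ± 0.08 for col1a2. The bone matrix gene sparc had a log2 fold change of -0.36 ± 0.08. These 4 genes were called by DESeq2 and not by edgeR, where their adjusted p-values were 0.0760, 0.0862, 0.0892 and 0.113. Adjusted over the list alone, edgeR counted 12 genes lower and 1 higher, and DESeq2 over all genes counted 5 lower and 1 higher. The list was called lower by camera (adjusted p = 2.21e-05), a call that was lost with adjusted p = 0.392 with an estimated correlation.

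Of the skeletal marker genes chosen before the data were examined, 10 were tested, 0 were called by edgeR and 2 (col1a1a and spp1) by DESeq2, and 9 had negative fold changes. The osteoblast transcription factor genes runx2b and sp7 had log2 fold changes of -0.11 ± 0.11 and -0.12 ± 0.22, no larger than their standard errors. The matrix genes spp1, alpl and col10a1a had values of -0.66 ± 0.16, -0.24 ± 0.08 and -0.37 ± 0.12. The cartilage genes sox9a and col2a1a had values of -0.08 ± 0.11 and -0.15 ± 0.13. The bone resorption genes ctsk and acp5a had values of 0.69 ± 0.41 and -0.11 ± 0.20. The cartilage list (30 tested, 0 called, 23 negative) was called lower by camera (adjusted p = 0.00723; adjusted p = 0.378 with an estimated correlation), as was collagen processing and crosslinking (29 tested, 0 called, 23 negative; adjusted p = 0.000779; adjusted p = 0.392 with an estimated correlation). Adjusted over the list alone, both counted 0 genes. Without SP_H replicate 3 both list calls were lost (adjusted p = 0.0789 and 0.0515), and without SP_L replicate 2 that of cartilage was (adjusted p = 0.0717). The median of the cartilage list relative to all genes went from -0.11 to -0.21 without SP_H replicate 2, and that of collagen processing from -0.15 to -0.06 without SP_L replicate 2. The lists for osteoclasts (18 tested, adjusted p = 0.882) and for vitamin D, calcium and phosphate regulation (21 tested, adjusted p = 0.970) were not called and also counted 0 genes adjusted over the list alone.

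Of the 6 lists of lipid genes, camera called 3 higher in SP_L, 0 with an estimated correlation, and 3 were not called. EdgeR called 0 genes in each of the 6 lists and DESeq2 between 0 and 7. Of the 35 tested fatty acid oxidation genes, 31 had positive log2 fold changes with a median of 0.28 (0.15 with library size alone). They included acaa2 at 0.67 ± 0.11, crata at 0.85 ± 0.15, hadhab at 0.54 ± 0.12 and acadm at 0.47 ± 0.10. None passed edgeR over all genes (crata did without SP_H replicate 1, adjusted p = 0.0399), 13 did when adjusted over the list alone, and DESeq2 called 7, all higher. The list was called higher by camera (adjusted p = 6.80e-08; adjusted p = 0.354 with an estimated correlation). Of 24 genes of cholesterol synthesis, 20 were positive with a median of 0.31, among them hmgcs1 at 0.60 ± 0.15 (camera adjusted p = 9.61e-05; adjusted p = 0.392 with an estimated correlation); edgeR called 0, also adjusted over the list alone, and DESeq2 called 2. Of 43 lipoprotein and lipid transport genes, 32 were positive, among them the lipid droplet gene plin2 at 0.94 ± 0.16 (camera adjusted p = 0.00196; adjusted p = 0.510 with an estimated correlation); edgeR called 0 over all genes, 2 adjusted over the list alone, and DESeq2 called 1. This last list call was lost without SP_H replicate 3 (adjusted p = 0.399), where the list's median relative to all genes went from 0.23 to 0.06. That library stood apart in liver and gut markers as well: its scores (mean log2 CPM relative to all 6 libraries) were -0.437 for lipoproteins, -0.572 for bile acids, -0.484 for hepatocytes and -0.813 for enterocytes. The lipoprotein score of SP_H replicate 1 (0.132) was above every SP_L library. The lists for phospholipid synthesis (44 tested, camera adjusted p = 0.104), fatty acid synthesis (30 tested, 0.104) and bile acids (18 tested, 0.146) were not called, with 1, 0 and 0 genes higher adjusted over the list alone. Without SP_L replicate 3 the phospholipid and fatty acid synthesis lists were called higher (adjusted p = 0.0369 and 0.0479). The bile acid list was called higher with library size alone (adjusted p = 0.0313) and without SP_H replicate 1 (0.00721), where its median relative to all genes went from 0.16 to 0.38. Within the phospholipid list the methionine cycle gene bhmt, which uses betaine, had a log2 fold change of 0.66 ± 0.10 and was called by DESeq2 but not by edgeR.

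**Figure D2:**
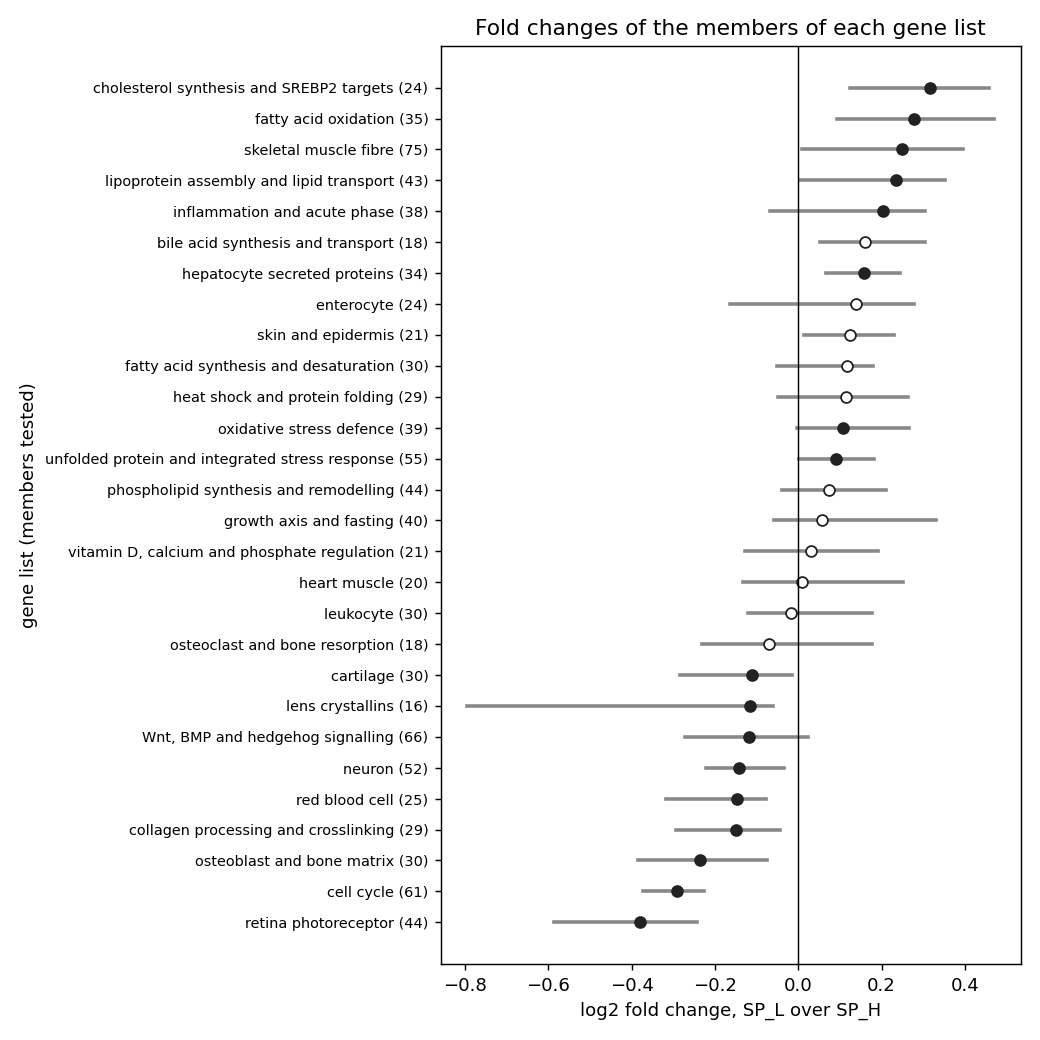
Log2 fold change (SP_L over SP_H, horizontal axis) of the tested members of 28 gene lists, with the number of members in parentheses; points are medians, bars run from the first to the third quartile, and filled points mark the 17 lists called by camera with a preset correlation. The retina photoreceptor and cell cycle lists have the lowest medians, -0.38 and -0.29, and 0 lists are called with an estimated correlation.

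By camera the skeletal muscle fibre list was called higher and the retina photoreceptor list lower in SP_L, calls that were lost with an estimated correlation. Of 75 tested skeletal muscle fibre genes, 57 were positive with a median of 0.25 (0.12 with library size alone as the scaling). One of them, ckma, rose by the edgeR test; adjusted over the list alone 26 were higher and 1 lower, and DESeq2 called 15 higher and 1 lower. The list was called higher by camera (adjusted p = 6.80e-08; adjusted p = 0.378 with an estimated correlation). Its genes took 13.9 ± 0.675% of all counts in SP_H and 16.4 ± 0.851% in SP_L (SD, n = 3 each). The heart muscle list was not called (10 positive, 10 negative, camera adjusted p = 0.840), and a slow muscle fibre list, chosen after the data were seen, had 11 of 15 negative values (adjusted p = 0.00568; adjusted p = 0.145 with an estimated correlation). No test compared these lists with the skeletal muscle fibre list. Of 44 retina photoreceptor genes, 43 were negative with a median of -0.38, including the cone arrestin gene arr3a at -0.66 ± 0.15 and rlbp1b at -0.68 ± 0.13. Among them edgeR called 0, 18 were lower adjusted over the list alone, and DESeq2 called 8 lower (camera adjusted p = 5.21e-14; adjusted p = 0.392 with an estimated correlation).

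Among other tissue markers, the red blood cell, neuron and lens lists were called lower and the hepatocyte list higher in SP_L by camera, 0 of them with an estimated correlation. The red blood cell list (25 tested, 21 negative) included the globin gene hbae5 at -0.75 ± 0.12 and was called lower (camera adjusted p = 0.000628; adjusted p = 0.354 with an estimated correlation); adjusted over the list alone 3 genes were lower and 1 higher, the same counts as by DESeq2. The neuron list (52 tested, 42 negative) was called lower (adjusted p = 0.000390; adjusted p = 0.438 with an estimated correlation), with 2 genes lower adjusted over the list alone. The lens list (16 tested, 13 negative) was called lower (adjusted p = 0.00348; adjusted p = 0.510 with an estimated correlation), with 4 lower adjusted over the list alone. Its median relative to all genes was -0.12 with all libraries. The call was lost without SP_H replicate 3 (median -0.05, adjusted p = 0.0832), without SP_L replicate 2, where the median turned positive (0.02, adjusted p = 0.123), and on log2(FPKM + 0.1) (adjusted p = 0.0663). The median was -0.23 without SP_H replicate 2, -0.53 without SP_L replicate 1 and -0.07 without SP_L replicate 3. The hepatocyte list (34 tested, 28 positive) was called higher (adjusted p = 0.0199; adjusted p = 0.696 with an estimated correlation), with 1 gene higher and 1 lower adjusted over the list alone. Without SP_H replicate 3 its direction turned (median relative to all genes -0.05 against 0.16, adjusted p = 0.439), without SP_L replicate 2 its call was lost (adjusted p = 0.168), and without SP_H replicate 1 the median was 0.32. The score of SP_H replicate 3 was -0.484 for hepatocytes and -0.813 for enterocytes, the lowest of the 6 libraries in both. Lists for skin (21 tested, camera adjusted p = 0.275), enterocytes (24, 0.882), leukocytes (30, 0.920) and heart muscle (20, 0.840) were not called, and the last 2 had medians of -0.02 and 0.01, opposite in sign to the test. Adjusted over the list alone, 2 heart muscle genes were lower and 0 genes passed in the other 3 lists. Only 4 exocrine pancreas genes were tested, too few for a list test.

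The cell cycle list was called lower in SP_L by camera (adjusted p = 4.59e-15), a call that was lost with adjusted p = 0.354 with an estimated correlation. Of 61 genes tested, 59 had negative log2 fold changes with a median of -0.29, including the proliferation marker mki67 at -0.51 ± 0.09 and top2a at -0.48 ± 0.09. None passed edgeR over all genes, 2 were lower adjusted over the list alone, and both were called by DESeq2. The Wnt, BMP and hedgehog signalling list (66 tested, 46 negative) was called lower (adjusted p = 0.000628; adjusted p = 0.392 with an estimated correlation). The unfolded protein and integrated stress response list (55 tested, 41 positive), which holds trib3, was called higher (adjusted p = 0.0133; adjusted p = 0.469 with an estimated correlation). The inflammation list (38 tested, 26 positive; adjusted p = 0.00309; adjusted p = 0.392 with an estimated correlation) and the oxidative stress list (39 tested, 29 positive; adjusted p = 0.0157; adjusted p = 0.492 with an estimated correlation) were also called higher, with 0 genes called by edgeR in either. Adjusted over the list alone, edgeR counted 1 stress response gene higher and 1 lower, and 0 genes in the signalling, inflammation and oxidative stress lists. The stress response call was lost without SP_H replicate 2 (adjusted p = 0.0525), without SP_L replicate 1 (0.220), with library size alone (0.0932) and in the 3 FPKM fits (0.0686, 0.0646 and 0.247). The oxidative stress call was lost without SP_H replicate 3 (adjusted p = 0.131), SP_L replicate 1 (0.103) and SP_L replicate 2 (0.168), and in the 3 FPKM fits (0.0603, 0.0516 and 0.0949). Relative to all genes, the stress response median of 0.09 became 0.04 without SP_L replicate 1 and 0.14 without SP_L replicate 3. The oxidative stress median of 0.10 became 0.16 without SP_H replicate 1, 0.04 without SP_L replicate 2 and 0.23 without SP_L replicate 3. The heat shock list (29 tested, adjusted p = 0.0674) and the growth axis and fasting list (40 tested, adjusted p = 0.0761), which holds fbxo32, were not called, with 1 and 2 genes higher adjusted over the list alone. The heat shock list was called higher with limma-voom (adjusted p = 0.0352), without SP_H replicate 3 (0.0411) and without SP_L replicate 3 (0.0333; median relative to all genes 0.07 against 0.11). The growth axis list was called higher with library size alone (adjusted p = 0.0183), on filtered FPKM (0.00541 and 0.00459), without SP_H replicate 1 (0.0140) and without SP_L replicate 1 (0.00364). Its median relative to all genes, 0.05, was 0.13 and 0.12 without these libraries.

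**Figure D3:**
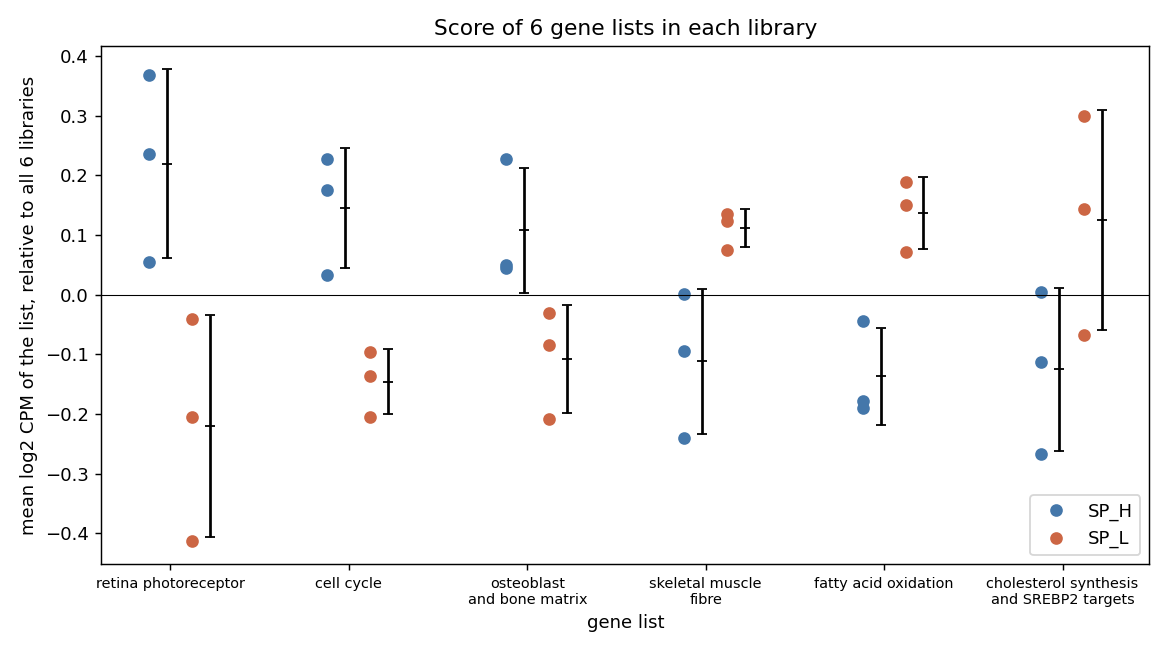
Mean log2 CPM of the members of 6 gene lists in each library, relative to the mean of all 6 libraries (vertical axis); points are libraries and bars the mean ± SD of 3. Groups do not overlap for 5 of the lists and overlap for cholesterol synthesis.

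Over all lists, camera with a preset inter-gene correlation called 17 of 28, 8 higher and 9 lower, and with an estimated correlation it called 0. Regrouping the same 6 libraries into other sets of 3 and 3, which mix the groups, gave between 5 and 14 called lists. Such mixed sets keep part of the difference between the groups. They therefore cannot show whether a call by the preset test is specific to that difference. An exact permutation test of 3 libraries against 3 cannot give a p below 0.10. Library scores did not overlap between groups in 12 of all 28 lists and in 10 of the 17 called ones. The called lists were selected by the same libraries, so this is no separate evidence.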

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

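Robust variance estimation and the fit without the 20 most abundant genes were chosen after seeing the data; the other alternatives were fixed before. The gene count is the least stable result. Against 14 genes called, 12 of them higher and 10 with a fold of at least 2, DESeq2 gave 449, 326 and 72, no filter 57, 48 and 19, library size alone 5, 3 and 4, and robust variance estimation 78, 62 and 14. Without the 20 most abundant genes the counts were 12, 11 and 10; ckma is one of the genes left out. A test against a fold of 1.5, by edgeR's glmTreat, called 0 genes in each count (263 at an unadjusted p under 0.05). Limma on log2 FPKM with either pseudocount or without a filter called 0, 0 and 0 (3383, 3374 and 3881 at an unadjusted p under 0.05). The FPKM fits use no TMM scaling. Their median log2 fold changes of all genes were -0.10, -0.12 and -0.07, against -0.13 with library size alone. The cause of the lost calls was not tested. Leaving out 1 library gave between 0 and 22 genes (0 without SP_H replicate 3 and without SP_L replicate 1, 22 without SP_H replicate 1). Between 0 and 17 were higher, and between 0 and 17 had a fold of at least 2. Such fits also have fewer libraries, and the cause was not tested. Of the 14 calls, limma-voom kept 13, robust variance estimation 12 (fbxo32 was lost, adjusted p = 0.124), and DESeq2 all 14; all 14 kept their sign in every alternative that tested them. The replicate block gave 2 genes, 2 higher and 2 with a fold of at least 2, and ended the calls of fbxo32, trib3, ckma and zgc:112285 (adjusted p = 0.108, 0.105, 0.108 and 0.108), with log2 fold changes of 2.87, 0.98, 0.78 and -1.20. Same-numbered libraries had deviations correlated at -0.10, -0.10 and -0.12, so the numbers share no more than a label. Camera called between 13 and 20 lists over the other settings, 0 with an estimated correlation and 18 by fry's mixed test; fry's directional test called 0 (smallest adjusted p = 0.0773). The mixed test left out the cartilage, cholesterol, lipoprotein, hepatocyte and oxidative stress lists and added osteoclasts, phospholipid and fatty acid synthesis, heart muscle, heat shock and growth axis. These tests ask different questions. Camera with an estimated correlation and both fry tests allow for members that vary together. The retina, cell cycle, bone, muscle and fatty acid oxidation lists kept their camera call in all settings with the preset correlation. So did the red blood cell, neuron, inflammation, cholesterol synthesis, and Wnt, BMP and hedgehog signalling lists. The FPKM fits ended the calls of the stress response and oxidative stress lists, log2(FPKM + 0.1) that of the lens list (adjusted p = 0.0663), and library size alone that of the stress response list (adjusted p = 0.0932), while bile acids and growth axis gained one (0.0313 and 0.0183). Of the named genes not called by edgeR, DESeq2 called 45, robust variance estimation 12, no filter 8 and limma-voom 1. Reversals of direction by camera were, apart from the hepatocyte list, in lists that were not called; values are medians relative to all genes, which can differ in sign from the test. For heart muscle they were 0.00724 with library size alone, 0.0250 with the block, and 0.0534, 0.0641 and 0.0219 in the FPKM fits. For vitamin D regulation they were 0.0316 with limma-voom, 0.0229 with the CPM filter, and -0.0351 and -0.0426 on filtered FPKM. For leukocytes they were -0.0294 with limma-voom and -0.0495 on unfiltered FPKM, for enterocytes 0.135 with the CPM filter, and for osteoclasts -0.0603 and -0.0531 on filtered FPKM. Leaving out 1 library gave ranges of -0.0323 to 0.0384 for heart muscle, -0.0776 to 0.0443 for vitamin D regulation, -0.0908 to 0.0793 for leukocytes, -0.208 to 0.356 for enterocytes, -0.0690 to 0.0103 for osteoclasts, -0.0249 to 0.382 for bile acids, -0.0119 to 0.201 for skin and -0.0495 to 0.319 for the hepatocyte list, whose call turned without SP_H replicate 3 (-0.0495) and was lost without SP_L replicate 2. The log2 fold change of sp7 ranged from -0.27 to 0.14, positive without SP_H replicate 3. The cause was not tested. Product-name matching of lists was not run as an alternative, because no product names were available to match. Replicates differed by 11 to 15 times the sampling variance, and what depth limits was not tested.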

Other observations

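The gene lists, genes and tests in this part were chosen after the results were seen, except that the test of gene length was set down before its own result was seen. Outside the fixed lists, 5 further gene groups had a majority of members of one sign, as small as 15 of 24 in glycolysis. In each, edgeR called 0 genes and DESeq2 between 0 and 4. All 74 cytosolic ribosomal protein genes had positive log2 fold changes (median 0.14; camera adjusted p = 1.49e-11, adjusted p = 0.398 with an estimated correlation), as did 53 of 56 subunits of complex I, complex II and ATP synthase (median 0.18; 3.24e-09 and 0.398), 34 of 38 proteasome genes (0.12; 0.00301 and 0.460) and 15 of 24 glycolysis genes (0.16; 0.0256 and 0.460). In these 4 lists SP_L replicate 1 had the highest library scores (mean log2 CPM relative to all 6 libraries), 0.152, 0.208, 0.121 and 0.191. The scores of SP_L replicates 2 and 3 were 0.0444 and 0.0309 for ribosomal proteins, 0.0179 and 0.0448 for the respiratory subunits, -0.0127 and -0.00992 for the proteasome, and -0.126 and 0.0973 for glycolysis. Glycolysis in SP_L replicate 2 lay below every SP_H library, and proteasome scores overlapped too. Without SP_L replicate 1 the medians were 0.10, 0.11, 0.03 and 0.07, and the proteasome and glycolysis calls were lost (camera adjusted p = 0.238 for both). The glycolysis call was also lost without SP_H replicate 1 (0.0629), SP_H replicate 3 (0.0571) and SP_L replicate 3 (0.0895). Slow muscle fibre genes had 11 of 15 negative values (median -0.13; 0.00568 and 0.145), with a median of -0.20 without SP_L replicate 1. Gene length, weighed below, was not checked for these 5 groups.

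Retinal interneuron genes other than those called by DESeq2 had 24 of 26 negative values (median -0.36; camera adjusted p = 2.93e-08, adjusted p = 0.145 with an estimated correlation), and pigment cell genes other than pmelb and tyrp1b had 16 of 20 (median -0.17; 0.0181 and 0.145). The pigment cell call was lost without SP_H replicate 3 (median -0.10, adjusted p = 0.0698) and SP_L replicate 3 (adjusted p = 0.0928), and its median was -0.26 without SP_L replicate 2. The bone genes bglapl, scpp7 and the collagen crosslinking gene loxa had log2 fold changes of -0.82 ± 0.22, -0.85 ± 0.21 and -0.80 ± 0.18, called by DESeq2 and not by edgeR.

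For the lower retina, cell cycle and bone lists and the higher muscle and fatty acid oxidation lists, gene length is argued against. After removing each library's trend with length, every one of the 5 medians kept at least 97.8% of its size. Over all tested genes, log2 fold change and length had a Spearman correlation of -0.13. Shorter genes thus tended to be higher in SP_L. The groups added after the data were seen, ribosomal proteins among them, were not checked for length. A few abundant genes taking more of the counts are argued against for these 5 lists, because such a shift moves all other genes alike. TMM scaling moved the median of all genes from -0.13 to 0.00. It moved the retina median from -0.51 to -0.38 and the muscle median from 0.12 to 0.25, so their gap stayed. The 5 medians had the same directions with library size alone, with TMM and without the 20 most abundant genes. Without those genes they were -0.38 (retina), -0.29 (cell cycle), -0.23 (bone), 0.21 (muscle) and 0.28 (fatty acid oxidation). The smallest with TMM or without those genes lay 3.43 SE from 0, by a bootstrap over genes that ignores correlation between them. The 5 lists were picked after their TMM values were seen, so this SE is no separate evidence that they changed. A first test, with library size alone, was void. A larger share of muscle lowering every other tissue alike stays open: the retina score changed by -0.53 ± 0.25 relative to skin, under the bound set for it, and a second test added after that, over all 55 pairs of 11 tissue lists, found 0 pairs past adjustment (smallest adjusted p = 0.469). Values against it were 5 pairs at an unadjusted p under 0.05 and 11 pairs without overlap between groups (chance gives 10%). By chance a share of 0.05 of the 55 pairs would be under that p. The 5 included retina minus leukocyte at -0.46 ± 0.13 and neuron minus leukocyte at -0.14 ± 0.04. The pairs reuse the same 11 lists, so they are not independent of each other. Diet, deformity, body size and developmental stage may each contribute and were not separable here.

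The gap between 449 DESeq2 calls and 14 edgeR calls was weighed next. No other split of these libraries into 3 and 3 gave as many DESeq2 calls: the highest count was 35. But every other split mixes the groups, which adds their difference to the spread. How many genes DESeq2 would call without a difference between the groups therefore stays open. The 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 14 edgeR calls against 1 at most in another, 449 DESeq2 calls against 35, and 17 called lists against 14, each with 1 split of 10 as large, the real one.

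A hypothesis was that p53 target genes rose as a group, because ccng1, cdkn1a and phlda3 had log2 fold changes of 0.98 ± 0.17, 0.49 ± 0.11 and 0.98 ± 0.14 (DESeq2 calls, not edgeR calls). The other 29 tested p53 targets gave no such call (16 positive, 13 negative, camera adjusted p = 0.700). Their median was 0.02 ± 0.05, with the SE from a bootstrap over genes. For a rise as a group it is a negative result. Fry's mixed test, which takes changes in either direction, gave these other targets an adjusted p of 0.0271. Changes of single members in either direction, and a response of those 3 genes without a rise of the rest, stay possible.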
